A study of Mus musculus with 2 samples.

How the data were processed

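Single-cell RNA sequencing was done on epithelial cells of mouse colon in 2 libraries, 1 per group. The library labelled whole epithelium came from c-Kit-creERT2 mice without treatment. The library labelled GFP came from c-Kit-creERT2;Rosa26-mTG mice, in which cells that had expressed the recombinase from the Kit gene, and their progeny, carry GFP. Those mice had 1 injection of tamoxifen (1 mg per 20 g body weight) and their GFP-positive cells were sorted. Per the labels' protocols, crypts were released with EDTA, dissociated enzymatically and loaded for droplet capture with the 3' v2 chemistry of 10x Genomics.

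The deposited matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger on genome build mm10, per the submitters' processing notes. Those notes name Cell Ranger 2.1.1, while the headers of both matrices name version 3.1.0, and the difference was not resolved. The matrices list barcodes called as cells, with call settings not given in the sources used here, and no normalisation. The gene lists of both libraries are identical and hold 31053 genes, with 71 symbols that occur more than once. The 2 matrices and the 2 barcode lists are crossed in the records. The matrix recorded under whole epithelium has 13575 columns, the number of barcodes recorded under GFP, and the matrix recorded under GFP has 13967 columns, the number of barcodes recorded under whole epithelium. By a rule fixed before the data were examined, each matrix was given to the sample of the barcode list of its size. Every direction reported here rests on that assignment and would turn with the reverse one, so the libraries are called by their labels.

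Barcodes were kept with at least 500 detected genes, at least 1000 UMIs and at most 25% mitochondrial UMIs. Scrublet, as implemented in scanpy 1.11.5 and run per library, called 2 cells (0.0258%) of the library labelled whole epithelium and 4 cells (0.0694%) of the library labelled GFP. This is under the 0.5% below which the caller was taken not to have worked, so doublets were kept. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and both libraries were clustered together on a graph of 15 neighbours with leidenalg 0.10.2 at resolution 1.0. This gave 38 clusters of 13529 cells, of which 30 drew over 95% of their cells from 1 library.

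Clusters were named from fixed markers of 15 cell classes. A cluster took the class with the highest mean log2 fold of its markers over the median cluster of the same library, with at least 3 markers raised at least 2-fold, and clusters led by markers of another class stayed unnamed. This mean is the marker score. Clusters with a score under 0.5, or with fewer than 20 cells in the library that held most of them, also stayed unnamed. Stem and cycling clusters were joined as stem/TA-like (stem or transit-amplifying), and goblet and deep crypt secretory clusters as goblet-like. Clusters whose median UMI count was under 1/3 of that of their library were named only from a marker score of 1.5 and with a marker of the class among their 10 leading genes. In this way 27 clusters were named. The markers were fixed beforehand, but the rule that scores them was settled after the data had been seen. In all 4 versions of it were run, the last 3 of them after class shares had been seen. The earliest allowed names from a single marker. The next asked for 3 markers and compared a cluster with the other cells of its library. The version kept compares it with the median cluster, because that reference does not move with the number of cells of a class in a library. The last asked for a score of 2.0 in shallow clusters and was put back. The choice matters. Against the other cells of the library the colonocyte-like share was 19.0% in the library labelled whole epithelium and 27.6% in the library labelled GFP, where the version kept gave 29.7% and 27.7%. The goblet-like share of the library labelled whole epithelium was 11.2% with either replaced setting and 13.6% with the version kept. Unnamed shallow clusters, which the score of 1.5 or the demand for a leading marker keeps out of the classes, held 15.3% of the kept cells of the library labelled whole epithelium and 24.3% of those of the library labelled GFP.

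UMIs were summed over kept cells, in the whole library and in each class with at least 100 kept cells in each library, and given as CPM, the UMIs of a gene scaled to a common total. With 1 library per group there is no replicate and no test, and no p-value was computed. Sums carry exact Poisson 95% intervals, log2 ratios carry exact conditional binomial intervals, and shares carry exact Clopper-Pearson intervals. All of them cover counting error only, neither animals nor library preparation, and those of sums and ratios leave out variation among cells. A gene with 0 UMIs in a library was set to a floor of 3 UMIs over that library, which makes its ratio a bound by convention, not the limit of the exact interval. Log2 ratios are the library labelled GFP over the library labelled whole epithelium. For the share of cells with a UMI, each cell was thinned to 2000 UMIs and shallower cells were left out. In each of 23 fixed gene lists the members with at least 20 UMIs were counted as higher or lower, and the median log2 ratio was placed as a percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

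Genes were named by a fixed rule of size. Among genes with at least 100 UMIs over both libraries, leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes and numbered gene models, the 12 largest log2 ratios in each direction were taken for the whole library and the 10 largest for each class. A ratio of at least 1.5-fold and separate Poisson intervals were required. Kit, Lgr5, Reg4 and Muc2 were always named, and 2 to 4 members of each list could be given. Some genes that the rule takes are not reported here. Gene positions are from GENCODE M21 on GRCm38, the assembly called mm10.

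The calculation was tested on simulated counts with 200 genes changed by known folds. In the whole library (12873 genes) the intervals separated 97.0% of genes changed 2-fold and 89.6% of those changed 1.5-fold, and in the enteroendocrine-like class (4307 genes) 88.1% and 50.7%. Of the unchanged genes, 0.473% were separated in the whole library. The simulated counts were Poisson draws from a profile pooled over both libraries, without variation among cells, animals or preparations. These rates therefore hold for counting error only and are not error rates for a comparison of different animals. The alternatives tried were a looser and a stricter cell filter, doublet removal, other cluster resolutions, each library clustered alone, classes by the highest marker score of each cell, thinning before clustering, TMM factors from edgeR 4.0.16, median-of-ratios size factors, equal weight per cell or per cluster, and other minimum counts and pseudocounts for the lists. Because doublets were kept, the alternative of keeping them equals the values reported. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3 were used.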

Results

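The data are 2 single-cell libraries of mouse colon epithelium, 1 of the whole epithelium and 1 of cells sorted as GFP-positive, which the labels give as descending from Kit-expressing cells. GFP and Cre sequences are not among the features used here, so the sort was not checked directly. The comparison asks which epithelial cells the Kit lineage gives rise to, and how they differ from the epithelium at large. The library labelled whole epithelium held 13967 barcodes with 164185392 UMIs, and the library labelled GFP held 13575 barcodes with 150348319 UMIs. The filter kept 7762 cells (55.6%) of the library labelled whole epithelium and 5767 cells (42.5%) of the library labelled GFP. Kept cells had a median of 14160 and 15821 UMIs and of 3368 and 3519 detected genes, in that order. All values come from 1 library per group, so no difference below has a replicate check, and the intervals are for counting error only.

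The animals behind the libraries differed in sex. Xist, the RNA that coats the inactive X chromosome, was at 0.0652 CPM in the library labelled whole epithelium and 749.8 CPM in the library labelled GFP. The Y-linked genes Ddx3y, Eif2s3y and Uty were at 35.4, 42.6 and 13.1 CPM in the library labelled whole epithelium and had no UMI in the library labelled GFP, and Kdm5d was at 16.0 CPM against 1 UMI. The sex-linked list had 2 members higher and 4 lower in the library labelled GFP. Gt(ROSA)26Sor, the RNA of the locus that holds the reporter allele in the mice of the library labelled GFP, was at 33.8 CPM in the library labelled whole epithelium and 1.14 CPM in the library labelled GFP (log2 ratio -4.89, interval -5.15 to -4.63). It was looked at as a check of the labels after its values had been seen, and goes with the assignment used if the reporter allele interrupts this RNA.

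Cells of each main epithelial class were present in both libraries. Colonocyte-like cells, the absorptive cells, made up 29.7% (28.7 to 30.7) of kept cells in the library labelled whole epithelium and 27.7% (26.5 to 28.8) in the library labelled GFP. Mucus-producing goblet-like cells made up 13.6% (12.8 to 14.3) and 18.2% (17.2 to 19.2). Stem/TA-like cells made up 20.2% (19.3 to 21.1) and 12.5% (11.7 to 13.4). Hormone-producing enteroendocrine-like cells made up 4.14% (3.70 to 4.60) and 1.89% (1.55 to 2.28), and tuft-like cells, the chemosensory cells, 0.451% (0.314 to 0.627) and 0.711% (0.511 to 0.963). Unnamed clusters held 28.4% and 37.9%, and 15.3% and 24.3% of kept cells were in shallow unnamed clusters. The lower enteroendocrine-like share in the library labelled GFP held under every alternative, from -3.36 to -1.12 percentage points. No alternative left out shallow named clusters as such, and in the clustering reported this difference lay in 2 of them. These were c28, with 97 cells of the library labelled whole epithelium and 2 of the library labelled GFP, and c29, with 87 and 0. The deeper clusters of the class, c22 and c32, held 104 and 33 cells against 97 and 10, of 7762 and 5767 kept cells. Their joint share was thus not lower in the library labelled GFP. The direction of the colonocyte-like (-14.81 to 8.58 points), goblet-like (-13.54 to 16.35) and stem/TA-like (-7.67 to 6.02) differences depended on the clustering, the filter or the naming, and the sort for GFP can itself set these shares.

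**Figure D1:**
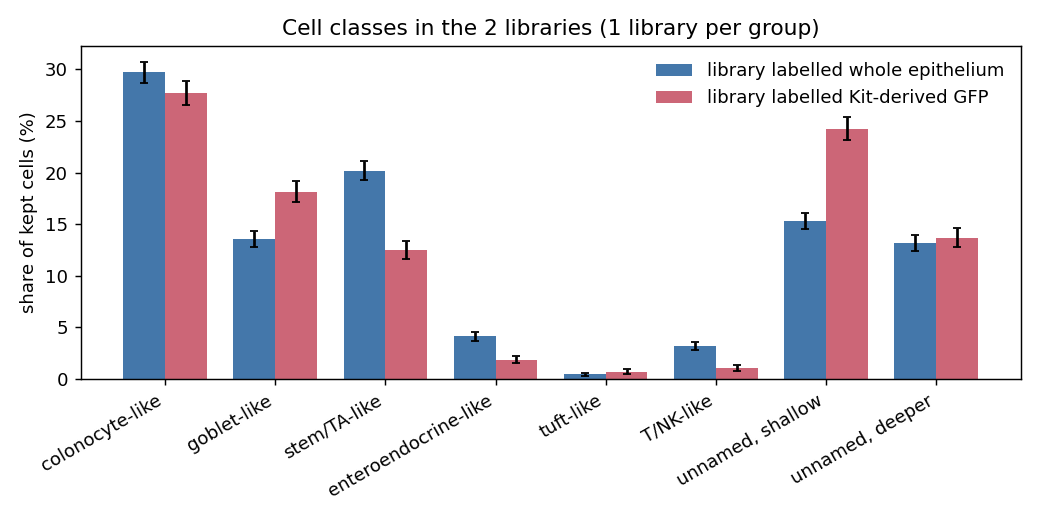
Share of kept cells (%) in each class for the library labelled whole epithelium (7762 cells) and the library labelled GFP (5767 cells); error bars are exact binomial 95% intervals, for counting error only. The enteroendocrine-like share was 4.14% against 1.89%, and the shallow unnamed share 15.3% against 24.3%.

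Over all kept cells, the goblet products Retnlb and Ang4 were much higher in the library labelled GFP, and the antibacterial lectin genes Reg3b and Reg3g, the T and NK cell genes Xcl1 and Gzma and the hormone gene Sst were lower. Retnlb (ENSMUSG00000022650, chromosome 16, 48816856 to 48818892), a goblet cell protein with activity against bacteria, was at 209.7 CPM in the library labelled whole epithelium and 8540 CPM in the library labelled GFP (log2 ratio 5.35, interval 5.33 to 5.36). Ang4 (ENSMUSG00000060615, chromosome 14, 51763878 to 51773590), an antimicrobial ribonuclease, was at 9.86 and 1130 CPM (6.84, 6.76 to 6.92). Reg3b (ENSMUSG00000071356, chromosome 6, 78370657 to 78373466) went the other way, from 9423 to 1282 CPM (-2.88, -2.89 to -2.87), and Reg3g had a log2 ratio of -1.62. Ang4, Reg3b, Reg3g, Pnp2, Sprr2h and Khdc1a have close paralogs, so their counts are less certain than their intervals.

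Other genes with large ratios in favour of the library labelled GFP were Strc (log2 ratio 6.94, 5.37 to 9.22), Tfap2a, Nr1h5, Dmrta2, Ddr2, Pla2g4c, Sprr2h, Onecut2 and Khdc1a, down to 4.63 for the last. Several of them rest on few UMIs, as Strc with 3 and 289. Pla2g4c, a phospholipase, was at 1.81 and 62.2 CPM. In the other direction stood Pnp2, a purine nucleoside phosphorylase, with 3457 UMIs against 6 (-8.82, -10.27 to -7.70). Xcl1 (-7.95) and Gzma (-6.02), genes of T and NK cells, the hormone gene Sst (somatostatin, -6.67) and the collagen gene Col1a2 (119 UMIs against 1) were also lower. Ooep, Klk8, Nrn1, P2ry10, Pdzd7 and Samsn1 had log2 ratios from -6.69 to -5.97. The imprinted gene Peg3 had 442 UMIs in the library labelled whole epithelium and none in the library labelled GFP. This is 116-fold lower if a floor of 3 UMIs is set (log2 ratio -6.86, with the exact interval reaching up to -6.55).

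Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722), the receptor whose promoter drives the recombinase per the labels, was at 15.2 CPM in the library labelled whole epithelium and 7.82 CPM in the library labelled GFP (log2 ratio -0.96, -1.07 to -0.84). Lgr5 (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), the marker of crypt base stem cells, was at 8.07 and 1.39 CPM (-2.54, -2.79 to -2.29). Muc2 (ENSMUSG00000025515, chromosome 7, 141690340 to 141754693), the main mucin of the colon, was at 2495 and 5207 CPM (1.06, 1.06 to 1.07). Reg4 (ENSMUSG00000027876, chromosome 3, 98222156 to 98236748), a marker of deep crypt secretory cells, was at 143.2 and 226.3 CPM (0.66, 0.63 to 0.69).

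Among the fixed lists, MHC class II, the genes of antigen presentation, stood highest in the library labelled GFP. All 7 measured members were higher (median log2 ratio 1.72, above all 10000 random lists), with Cd74 at 324.5 and 1047 CPM and H2-Aa at 68.8 and 326 CPM. Of 26 goblet genes 22 were higher (0.80, above all random lists), among them Clca1 (3.89) and Fcgbp (2.65), and all 13 measured tuft genes were higher (0.74, percentile 99.98), such as Avil (1.91). Tuft-like cells held 364046 UMIs in the library labelled whole epithelium and 716869 in the library labelled GFP, so their share and depth enter the tuft median. Antimicrobial genes were split, 9 higher and 8 lower (0.42). Of the distal Hox genes 7 were higher and 2 lower (0.39, percentile 99.7), with Hoxb13 lower (-0.38). Deep crypt secretory genes divided evenly at 5 and 5 (0.30, percentile 99.8), with Retnlb high and Kit low.

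Immediate early and heat shock genes, the list for dissociation stress, were lower in the library labelled GFP. Of 22 members 20 were lower (median -0.81, below all random lists), with Jun at 1703 and 967 CPM and Atf3 at 754.2 and 261.2 CPM. Interferon response genes were lower as well, 19 of 22 (-0.50, below all random lists), with Ifi27l2b at 521.4 and 30.8 CPM (-4.08) and Ifit2 at -2.84. Enteroendocrine genes were lower in 13 of 15 (-0.91, below all random lists), with Pyy at -0.59 and Neurog3, the transcription factor of endocrine progenitors, at -1.77. Genes of fatty acid oxidation and PPAR were lower in 19 of 25 (-0.29, below all random lists), with Pdk4 at -1.70. Notch pathway genes were lower in 12 of 14 (-0.26, percentile 1.73), with Hes1 at -0.67.

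The remaining lists lay closer to the other genes. Oxidative phosphorylation had 26 of 32 members higher with a small median (0.14, percentile 99.5), and glycolysis 11 of 13 (0.15, percentile 96.8). The unfolded protein response list had a median of 0.11 (percentile 96.1), with Calr at 0.16 and the stress regulator Ddit3 at -0.84. Kit signalling genes had a median of -0.17 (percentile 3.18) with 10 of 15 lower, oestrogen receptor targets -0.21 (percentile 8.53), xenobiotic metabolism -0.08 (percentile 8.29) and colonocyte genes -0.04 (percentile 15.1). Medians were 0.02 for the Lgr5 stem cell list (11 higher, 10 lower) and for the cell cycle list (15 and 14), 0.08 for Wnt targets and -0.03 for repair and fetal-like genes. The signs of the Lgr5 stem cell and Wnt medians were not stable, at -0.06 with at least 100 UMIs per gene and -0.01 with equal weight per cell.

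**Figure D2:**
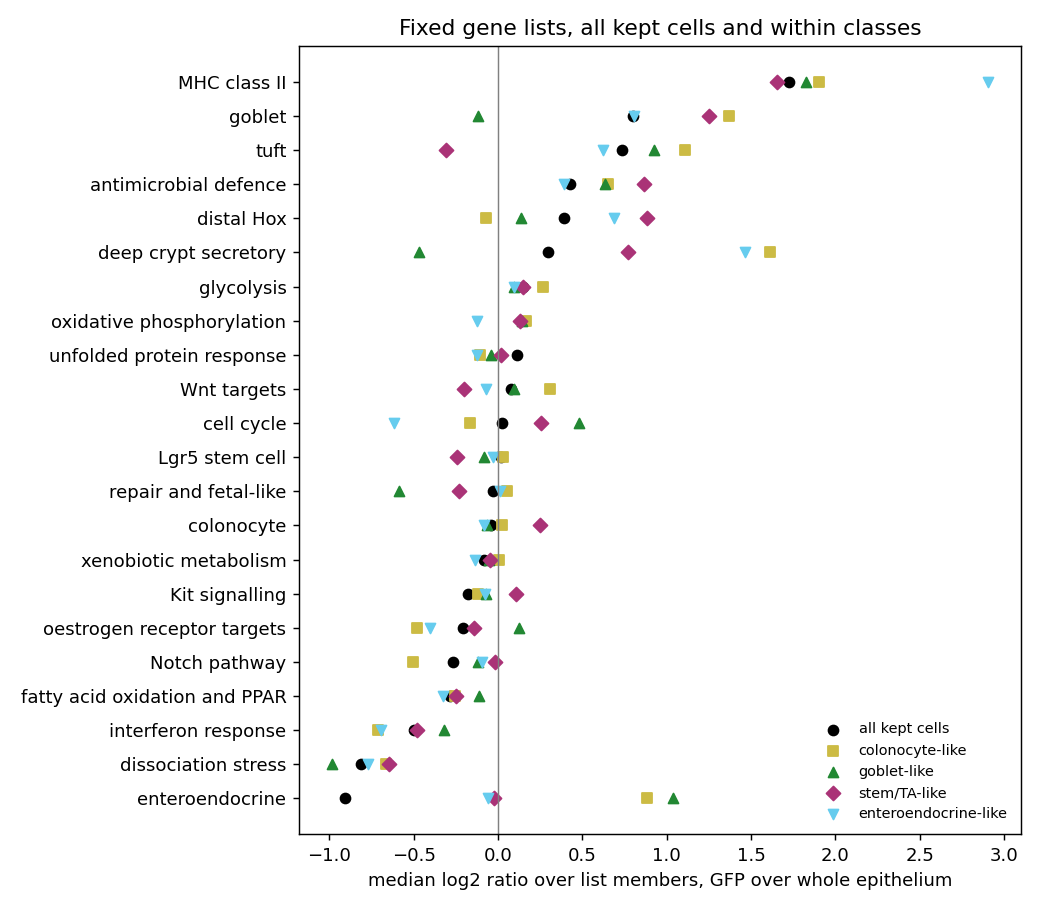
Median log2 ratio (library labelled GFP over library labelled whole epithelium) of the members of each fixed list, over all kept cells and within 4 classes; each point is a median over genes with 1 library per group, and lies right of 0 when the list is higher in the library labelled GFP. MHC class II was at 1.72 over all cells and dissociation stress at -0.81.

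Goblet-like cells of the library labelled GFP carried far more Retnlb and Ang4. Retnlb was at 1359 CPM in the 1052 goblet-like cells of the library labelled whole epithelium and 28498 CPM in the 1048 of the library labelled GFP (log2 ratio 4.39, 4.37 to 4.41). Ang4 was at 54.4 and 3801 CPM (6.13, 6.04 to 6.22), and Muc2 at 0.14 (0.13 to 0.14), or 0.76 with equal weight per cluster. In UMIs per cell, which also follow depth, Muc2 was at 286 and 470. Kit was lower, at 82.8 and 23.8 CPM (-1.80, -1.93 to -1.67), as was Reg4 (-0.27, -0.30 to -0.24) and Lgr5 (-1.73, -2.25 to -1.23). The class consists almost wholly of different clusters in the 2 libraries, c9, c23, c26 and c27 in the library labelled whole epithelium and c5, c24 and c25 in the library labelled GFP. Retnlb is among the leading genes of c9 and Ang4 among those of c5.

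Other named genes in goblet-like cells were Dmrta2, Pla2g4c, Ppy, Plxnd1 and the peroxidase gene Lpo (14.5 and 206.3 CPM) on the higher side, and Nr1h5 and Ddr2, which had no UMI in the library labelled whole epithelium. On the lower side were Pnp2, the imprinted RNA Meg3 (66.8 and 1.32 CPM), Gt(ROSA)26Sor, Gnai1, Ifi27l2b, Ido1, an enzyme of tryptophan breakdown (58.2 and 3.82 CPM), Stk26, Bex4, Fam71a and Btg3. The goblet list itself had 11 members higher and 15 lower (median -0.12, and 0.08 with equal weight per cell), with Clca1 at 2.96 and Fcgbp at 1.79. Cell cycle genes were higher in 24 of 29 (0.48, above all random lists), with Cenpa at 1.09. Repair and fetal-like genes were lower in 10 of 15 (-0.58), with Cldn4 at -2.72. Kit was unequal among the goblet-like clusters and the libraries overlapped: c5, c24 and c25 of the library labelled GFP were at 21.4, 25.6 and 89.2 CPM, and c9, c26, c23 and c27 of the library labelled whole epithelium at 108, 100.2, 38.2 and 28.6. With equal weight per cluster the log2 ratio for Kit was -0.58 and that for Reg4 turned to 0.12.

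Stem/TA-like cells of the library labelled GFP had less Lgr5 and more transcripts of goblet products. Lgr5 was at 19.9 CPM in the 1567 cells of the library labelled whole epithelium and 3.096 CPM in the 722 of the library labelled GFP (log2 ratio -2.68, -3.05 to -2.34). The Lgr5 stem cell list had 13 of 18 members lower (median -0.24, below all random lists), with Cdk6 at -1.27 and Slc12a2 at -0.23, and Wnt targets 10 of 14 (-0.20, percentile 0.28), with Ascl2 at -0.89. Retnlb was at 20.9 and 958.3 CPM (5.52, 5.42 to 5.61), Ang4 at 8.18 (7.55 to 8.89) and Clca1 at 5.10 (4.89 to 5.32), and 24 of 26 goblet genes were higher (1.25, above all random lists). Per cell, Retnlb was at 31.3 UMIs in these cells of the library labelled GFP (median depth 27526.5 UMIs), and at 20.9 in colonocyte-like (18556.5), 29.3 in enteroendocrine-like (3350), 23.5 in T/NK-like (1897) and 24.9 in shallow unnamed cells (1815), so it hardly followed depth in these classes, while tuft-like (69.4) and deeper unnamed cells (37.9) had more. Goblet products in cells other than goblet-like ones therefore need not come from those cells. In the library labelled whole epithelium the same classes had 0.286 to 0.872 UMIs per cell. Muc2 was at 1.55 (0.76 to 2.15 over the alternatives), Reg4 at 2.40 (0.79 to 3.62) and Kit at -0.88 (-1.31 to -0.25), with a counting interval of -1.32 to -0.46 for Kit. Distal Hox genes were higher in 6 of 7 (0.88, percentile 99.99), with Hoxb13 at 0.88 and Hoxd11 at 2.66, and cell cycle genes in 17 of 29 (0.26), with H2afz at 0.38 and Mcm4 at -0.78.

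The other genes named in stem/TA-like cells were Ddr2, Nr1h5, Dmrta2, Pla2g4c, Ppy, Plet1 (9.36 and 159.2 CPM) and Nos2, the inducible nitric oxide synthase (0.867 and 13.7 CPM), on the higher side. On the lower side were Pnp2 (1125 UMIs against 1), Lsmem1, Gt(ROSA)26Sor, the Wnt ligand gene Wnt5a (157 UMIs against 2), St3gal5, Bex4, Slc28a2, Pou3f1 and Mageh1. Sst had 1037 UMIs in these cells of the library labelled whole epithelium and none in those of the library labelled GFP. Over all kept cells of the library labelled whole epithelium it had 2334 UMIs, 978 of them in enteroendocrine-like cells. How many stem/TA-like cells carried this hormone gene was not examined, and doublets were kept. The class was made almost wholly of clusters c8, c11, c14 and c20 in the library labelled whole epithelium and of c12 and c16 in the library labelled GFP. Of these, c8 and c20 scored best as stem cells and the others, c12 and c16 included, as cycling cells, so the makeup of the class enters the medians of the Lgr5 stem cell list and of Wnt targets. Cluster c14 was led by MHC class II genes and Cxcl10.

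Colonocyte-like cells also differed in the same secreted products, in MHC class II and in interferon genes. Retnlb was at 16.5 CPM in the 2306 cells of the library labelled whole epithelium and 1024 CPM in the 1596 of the library labelled GFP (log2 ratio 5.96, 5.85 to 6.06), and Ang4 at 1.24 and 134 CPM (6.75, 6.36 to 7.17). Reg3b was at 13237 and 1264 CPM (-3.39, -3.40 to -3.37). S100a8, a neutrophil-associated calcium-binding protein also made by inflamed epithelium, was at 0.253 and 15.7 CPM, and Ceacam10 (5.20), Cd177 (4.64), Sprr2h (5.03), Khdc1a, Pla2g4c and Strc were higher as well. Dmrta2 had no UMI in the library labelled whole epithelium and 203 in the library labelled GFP. Lower were Pnp2 (-9.12), Sst, Ppp1r3e, Slc7a8, St3gal5, the interferon-inducible Ifi204 (15.8 and 0.398 CPM), Rin3, and Ugt8a and Pdzd7, which had 143 UMIs each against none.

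Interferon response genes were lower in 19 of 22 in colonocyte-like cells (median -0.71, below all random lists), with B2m at -0.73 and Ifit2 at -2.92, and MHC class II genes were higher in 7 of 7 (1.90). Goblet genes were higher in 23 of 26 (1.37, above all random lists), with Muc2 at 1.38 (1.35 to 1.42) and Reg4 at 2.09 (1.88 to 2.30). Per cell of the library labelled GFP, Retnlb, Ang4 and Muc2 were at 20.9, 2.74 and 13.1 UMIs, near the 24.9, 2.84 and 11.2 in its shallow unnamed cells, so these ratios need not come from colonocyte-like cells. Lgr5 had 28 and 4 UMIs (-2.40, -4.37 to -0.88), and Kit did not differ detectably at this depth (-0.59, -1.33 to 0.12). The colonocyte list itself had a median of 0.02, with Aqp4 at 1.33 and Slc37a2 at -2.16. Glycolysis genes were higher in 11 of 13 (0.27, percentile 99.6), with Pgk1 at 0.74. The median over all genes in this class was -0.14, and TMM or median-of-ratios scaling raised the log2 ratios by 0.11 and 0.13. Nearly all of the cells were in c2, c6, c10 and c13 in the library labelled whole epithelium and in c3, c7 and c15 in the library labelled GFP.

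**Figure D3:**
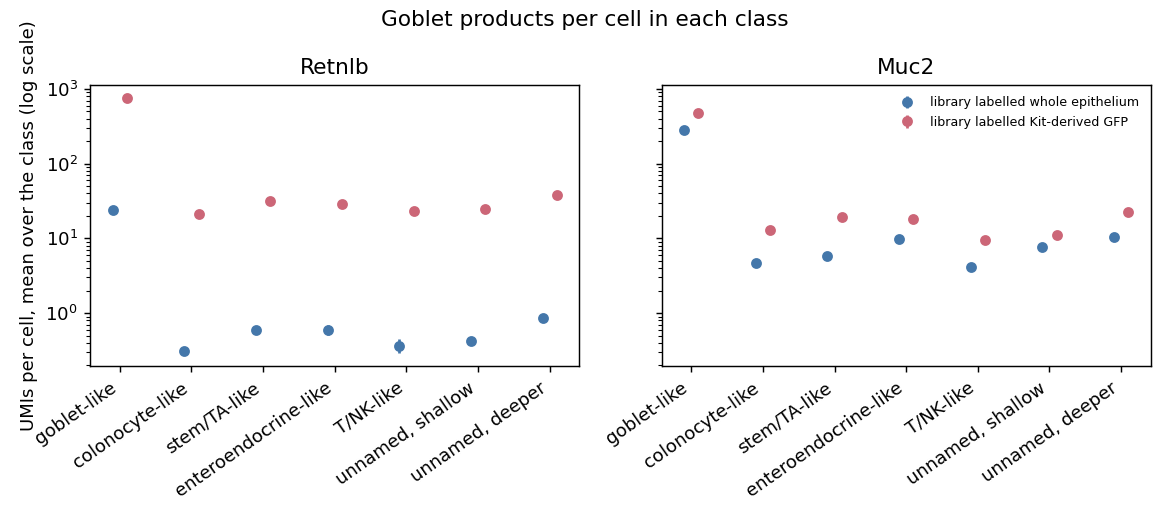
Mean UMIs per cell (log scale) of Retnlb and Muc2 in each class of the library labelled whole epithelium and the library labelled GFP, with exact Poisson 95% intervals. Retnlb in the library labelled GFP was at 762 UMIs per goblet-like cell and 20.9 per colonocyte-like cell, against 24.3 and 0.310 in the library labelled whole epithelium.

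Enteroendocrine-like cells, 321 and 109, differed in the hormones they expressed. Sst had 978 UMIs against 1 (log2 ratio -8.34, -13.65 to -5.86), and Nts, neurotensin, was at 1426 and 49.5 CPM (-4.85, -5.37 to -4.37). Ppy, pancreatic polypeptide, was at 69.8 and 1235 CPM (4.15, 3.89 to 4.41). How many cells carried these 3 hormone genes was not examined, and the intervals leave out variation among cells. Chgb (1.29) and Tph1 (1.61), the gene of serotonin synthesis, were higher, and the enteroendocrine list as a whole had a median of -0.06. Clusters c22 and c32 of the class held cells of both libraries, while c28 and c29 were almost all of the library labelled whole epithelium, so the makeup of the class enters these ratios. Retnlb (5.66), Ang4 (7.47), Clca1 (6.86), Mptx1, Clca4b and Fcgbp were higher, as were H2-Aa (3.64), H2-Ab1 (3.32) and H2-Eb1 (2.97). As in colonocyte-like cells, the ratios of the goblet products need not come from this class, with Retnlb at 29.3 UMIs per cell in the library labelled GFP against 24.9 in its shallow unnamed cells. Hmgn3, Peg3, S100g, Cadps, Tceal8, Fxyd4 and Ifi27l2b were lower, and cell cycle genes were lower in 23 of 29 (-0.61). Reg3b was at -4.30. In the library labelled whole epithelium its 49.2 UMIs per cell in this class lay between 71.6 in shallow unnamed cells and 11.6 in T/NK-like cells. Nearly all of those shallow cells were in c1, which has Reg3b among its leading genes. Whether the ratio for Reg3b comes from enteroendocrine-like cells therefore stays open. Muc2 was at 0.94 (0.86 to 1.02), Reg4 at 0.18 (0.03 to 0.34) and Kit at -1.04 (-2.25 to -0.02), and Lgr5 had 6 UMIs and 0. The ratio for Reg4 turned to -0.12 with the other naming reference and to -1.93 with equal weight per cluster, and that for Muc2 to -0.37 under the stricter mitochondrial filter.

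Across these 4 classes MHC class II genes were higher in the library labelled GFP, with medians from 1.66 to 2.90, and no measured member was lower. Dissociation stress genes were lower in each class, with medians from -0.98 in goblet-like to -0.64 in stem/TA-like cells, and interferon response genes with medians from -0.71 to -0.32.

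Among the 4 classes compared, Kit CPM was highest in goblet-like cells and Lgr5 CPM in stem/TA-like cells, and both were found in fewer of these cells in the library labelled GFP. Outside those classes, Kit was at 74.2 and 29.3 CPM in tuft-like cells (27 and 21 UMIs) and at 58.7 and 31.1 CPM in T/NK-like cells (85 and 5 UMIs), and Lgr5 at 33.0 and 9.76 CPM in tuft-like cells (12 and 7 UMIs). After thinning to 2000 UMIs, 15.3% (13.1 to 17.7) of goblet-like cells of the library labelled whole epithelium had a Kit UMI and 6.90% (5.42 to 8.64) of those of the library labelled GFP. Unthinned shares were 54.7% and 39.2%. In colonocyte-like cells, taken as background, Kit was at 0.501% and 0.189%, at median depths of 17460 and 18622 UMIs before thinning against 16855 and 24205.5 in goblet-like cells. Lgr5 was found in 3.82% (2.92 to 4.90) of stem/TA-like cells of the library labelled whole epithelium and 0.831% (0.306 to 1.80) of those of the library labelled GFP, with unthinned shares of 22.3% and 5.54% at median depths of 25772 and 27526.5. In colonocyte-like cells it was at 0.0912%, and at 0 of 1588 cells, where the floor of 3 would give a share of cells with a UMI of 0.189% and the exact interval reaches up to 0.232%. Ascl2 was in 4.27% and 2.08% of stem/TA-like cells. Smoc2 was in 8.93% (7.56 to 10.5) and 7.20% (5.43 to 9.34), a difference within counting error. Thinning left out 65 and 34 goblet-like, 22 and 0 stem/TA-like and 112 and 8 colonocyte-like cells.

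**Figure D4:**
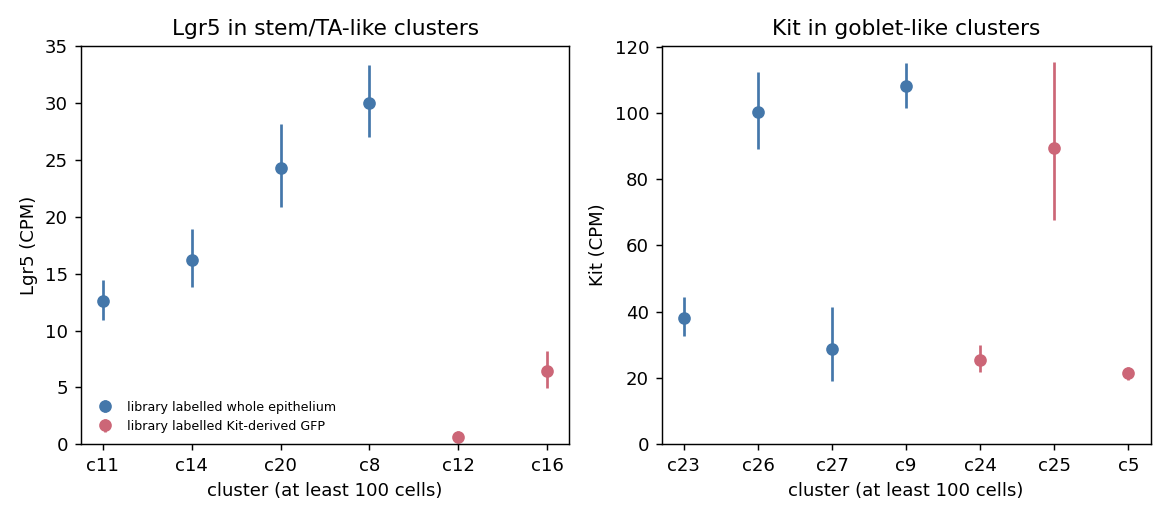
CPM of Lgr5 in stem/TA-like clusters and of Kit in goblet-like clusters of at least 100 cells, with exact Poisson 95% intervals; each cluster is drawn for the library that holds nearly all of its cells. Lgr5 was at 6.43 CPM in c16 of the library labelled GFP and at 12.6 CPM in c11, the lowest cluster of the library labelled whole epithelium.

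Cells in clusters named as non-epithelial were few, and fewer in the library labelled GFP. T/NK-like cells made up 3.17% (2.79 to 3.58) of kept cells of the library labelled whole epithelium and 1.06% (0.810 to 1.36) of the library labelled GFP. Their cluster was named from its cells of the library labelled whole epithelium. Stromal-like cells numbered 28 and 2, or 0.361% and 0.0347%. No cluster was named for mast cells or interstitial cells of Cajal, which also express Kit in the gut. The shallow cluster c0 (12 cells of the library labelled whole epithelium, 1396 of the library labelled GFP) scored best as B or plasma cells. It stayed unnamed, with no marker of that class among its leading genes, which included Zg16, Tff3 and Clca1. Under the looser filter 1 cluster was named as myeloid.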

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

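The tests of free RNA, of goblet cells caught with another cell and of handling were chosen only after the result was seen.

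A signal stood in barcodes outside the cell filter, part of which only the looser filter uses. In all barcodes outside the filter, Retnlb was at 4372 CPM (4371.8) in the library labelled GFP and at 81.9 CPM in the library labelled whole epithelium. In the same barcodes the haemoglobin gene Hbb-bs was at 1036 CPM (1036.3) in the library labelled whole epithelium and at 0.239 CPM in the library labelled GFP. Mitochondrial UMIs exceeded the limit of 25% in 57.5% of the barcodes of the library labelled GFP and in 38.2% of those of the library labelled whole epithelium.

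Retnlb and Ang4 were higher in the library labelled GFP in goblet-like cells and in every other class compared. Among goblet-like clusters of at least 100 cells the lowest of that library in Retnlb (c25, 12887 CPM) lay above the highest of the library labelled whole epithelium (c9, 2435 CPM) by a log2 ratio of 2.40 (2.37 to 2.44). With the Retnlb UMIs per cell of shallow unnamed clusters taken off, it was still 1.34 (1.29 to 1.39). This argues against free RNA at that level as the whole cause, but not at the level of tuft-like cells (69.4 UMIs per cell). Those had more Retnlb per cell than c25, which had 8375 UMIs in 176 cells. The order of c25 above c9 had been set beforehand as the outcome against goblet cells of different kinds. It cannot decide this, as the libraries share almost no goblet-like cluster. Cluster c24 of the library labelled GFP and c26 of the library labelled whole epithelium shared leading genes such as Sval1, Reg4 and Mptx1. Retnlb was at 15930 and 91.6 CPM in them, though c24 scored best as deep crypt secretory cells and c26 as goblet cells. Only c26 of the pair had Clca1, Fcgbp, Tff3 and Zg16 among its leading genes. Goblet cells of different kinds stay open. Removing the cells with the top 10% of doublet scores left 102% of the Retnlb CPM of colonocyte-like cells, which decides nothing because Scrublet did not work here, but goblet cells caught with another cell are no whole account of Retnlb in the other classes, since at least 79.6% (76.5 to 82.5) of the cells of each such class compared in the library labelled GFP had a Retnlb UMI after thinning. Free RNA from goblet cells may account for Retnlb outside them and stays open. Retnlb UMIs per cell were alike in shallow T/NK-like (23.5) and deep colonocyte-like cells (20.9), as free RNA would give, but higher in tuft-like cells (69.4). Over 18 goblet genes the log2 difference between T/NK-like and colonocyte-like cells had a median absolute deviation of 0.588, between the limits of 0.5 and 1 set for and against a single source. This deviation decides nothing, because the T/NK-like cells of the library labelled GFP held only 160568 UMIs. Genes of low CPM rest on few UMIs there, so counting error enters the deviation. Sex, genotype, tamoxifen, the sort and the animal differ between the libraries together, and none of them was tested.

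Immediate early and heat shock genes were lower in each class of the library labelled GFP, with class medians of -0.64 or below. Damaged cells with many mitochondrial UMIs are not a likely source, because the median over all cells was -0.88 without cells above 10% mitochondrial UMIs and -0.81 with them. Handling of the suspensions, such as the sort, and the group itself could each shift these genes in every class, in a direction that was not tested. They cannot be told apart with 1 library per group. The Kit lineage, as the biological difference in the design, was not tested apart from handling.

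Lgr5 was lower in stem/TA-like cells of the library labelled GFP. The tables argue against depth, since the share of cells with an Lgr5 UMI after thinning differed by -2.99 percentage points. The highest cluster of that library (6.43 CPM) lay below the lowest of the library labelled whole epithelium (12.6 CPM), with a log2 ratio of -0.97 (-1.40 to -0.56), though both scored best as cycling cells. This order of clusters had been set beforehand as the outcome against cells of different kinds. Clusters c16 of the library labelled GFP and c20 of the library labelled whole epithelium also shared leading genes such as Trf, Ttr and Fut9. Lgr5 was at 6.43 and 24.3 CPM in them, though only c20 scored best as stem cells. Cells of different kinds stay open all the same, since the libraries share almost no cluster of this class and those that scored best as stem cells were in the library labelled whole epithelium alone. The Kit lineage, sex, genotype, tamoxifen and the sort stay open and untested.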

How the results depend on the processing

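The alternatives chosen only after the result was seen were to leave out shallow unnamed clusters, to remove the top 10% of doublet scores, to remove the cells called by Scrublet, to name clusters against the other cells of the library, and to ask a higher score of shallow clusters. No paired analysis was possible because the results come from no test and each group has 1 library. The reverse assignment of the matrices was not run, since it changes the sign of every difference.

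Genes named for their size kept their direction in every alternative run: 191 values over all cells, 174 in colonocyte-like, 176 in goblet-like, 178 in stem/TA-like and 177 in enteroendocrine-like cells. A change of sign was unlikely for genes chosen for such large ratios, so this is a weak check. Those counts also include the alternative of keeping doublets, which equals the values reported. Kit and Lgr5 kept their direction as well, over all cells and in colonocyte-like, goblet-like and stem/TA-like cells. Of 132 values of list medians over all cells 130 kept their sign, and of 528 within classes 501. The log2 ratio of Retnlb ranged from 5.31 to 5.54 over all cells. The shares of enteroendocrine-like and T/NK-like cells stayed lower in the library labelled GFP, while the direction of the colonocyte-like, goblet-like, stem/TA-like and unnamed shares depended on the processing. In the clustering reported, the lower enteroendocrine-like share rested on the shallow clusters c28 and c29. Tuft-like cells were not found as a cluster under the stricter filter. Depth limits the enteroendocrine-like class most, with 109 cells in the library labelled GFP. For the differences that follow, the cause was not tested.

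Differences in shares are in percentage points, the library labelled GFP minus the library labelled whole epithelium, and were reported as -2.03 for colonocyte-like, 4.62 for goblet-like, -7.67 for stem/TA-like, -2.25 for enteroendocrine-like and 9.51 for unnamed cells. With clusters named against the other cells of the library they were 8.58 for colonocyte-like, 6.95 for goblet-like, -1.12 for enteroendocrine-like and -4.56 for unnamed cells. With a higher score asked of shallow clusters they were 6.95 for goblet-like and 7.17 for unnamed cells. Without the 6 cells called by Scrublet they were 3.79 for colonocyte-like, -3.80 for stem/TA-like and -0.36 for unnamed cells. At a resolution of 0.5 they were -4.53 for colonocyte-like, 0.025 for stem/TA-like and 5.34 for unnamed cells, and at 2.0 they were 0.55 for colonocyte-like, -6.56 for goblet-like and 0.90 for stem/TA-like cells. Under the stricter mitochondrial filter they were -14.81 for colonocyte-like, 6.90 for goblet-like, -4.69 for stem/TA-like, -2.81 for T/NK-like and 18.40 for unnamed cells. Without the top 10% of doublet scores they were -6.81 for colonocyte-like, 0.80 for goblet-like and 16.57 for unnamed cells. With cells thinned to 1000 UMIs before clustering they were -5.27 for colonocyte-like, -13.54 for goblet-like, 6.02 for stem/TA-like and 17.33 for unnamed cells. Without shallow unnamed clusters they were 1.47 for colonocyte-like, 7.99 for goblet-like and 2.55 for unnamed cells. With each library clustered on its own they were 0.68 for goblet-like and -3.70 for stem/TA-like cells. With the highest marker score of each cell they were 16.35 for goblet-like, -3.36 for enteroendocrine-like and 1.05 for tuft-like cells. Under the looser filter the stem/TA-like difference was -5.98.

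Log2 ratios of the genes named in every class moved as well. The stricter mitochondrial filter gave Reg4 0.81 and Muc2 1.20 over all cells, Reg4 -0.34, Kit -2.03 and Muc2 0.033 in goblet-like, Muc2 1.60 in stem/TA-like, and Reg4 0.35, Kit -2.39 and Muc2 -0.37 in enteroendocrine-like cells. The looser filter gave Muc2 1.04 over all cells and 1.55 in colonocyte-like, Reg4 -0.32 and Muc2 0.10 in goblet-like, Reg4 0.79 and Muc2 0.76 in stem/TA-like, and Muc2 1.18 in enteroendocrine-like cells. Without the top 10% of doublet scores Muc2 was at 1.54 in colonocyte-like cells, Reg4 at -0.12, Kit at -1.63 and Muc2 at 0.36 in goblet-like, Reg4 at 3.62, Kit at -0.25 and Muc2 at 2.15 in stem/TA-like, and Reg4 at -0.049 and Muc2 at 0.78 in enteroendocrine-like cells. Naming against the other cells of the library gave Reg4 1.75 and Muc2 1.14 in colonocyte-like, Reg4 -0.32 and Muc2 0.10 in goblet-like, and Reg4 -0.12 in enteroendocrine-like cells. Without shallow unnamed clusters Muc2 was at 1.05 over all cells.

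Median-of-ratios size factors gave Reg4 0.69 and Muc2 1.09 over all cells, and Muc2 1.51 in colonocyte-like, 0.13 in goblet-like and 1.47 in stem/TA-like cells, and TMM factors gave Muc2 1.09, 1.49, 0.13 and 1.47 in the same order. With equal weight per cell, values over all cells were 0.62 for Reg4, -0.76 for Kit and 0.89 for Muc2. In the same setting colonocyte-like cells had Reg4 at 1.71, Kit at -1.35 and Muc2 at 0.98, and goblet-like cells Reg4 at -0.044, Kit at -1.09 and Muc2 at 0.34. Stem/TA-like cells then had Reg4 at 2.02 and Muc2 at 1.27, enteroendocrine-like cells Reg4 at 0.0067 and Muc2 at 0.65, and the oxidative phosphorylation list a median of 0.21. With equal weight per cluster Reg4 was at 1.88 and Muc2 at 1.16 in colonocyte-like, Reg4 at 0.12, Kit at -0.58 and Muc2 at 0.76 in goblet-like, and Reg4 at -1.93 and Muc2 at 1.32 in enteroendocrine-like cells. By construction the shares of cells with a UMI fall with thinning: the difference for Kit in goblet-like cells was -4.74 points at 1000 UMIs and -15.44 unthinned, and that for Lgr5 in stem/TA-like cells -16.80 unthinned.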

Other observations

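No test was run for this part, and all genes in it were chosen after their values were seen.

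Defence and hormone genes beyond those named for size also differed over all kept cells. Itln1, an intestinal lectin that binds microbial sugars, was at 1.46 CPM in the library labelled whole epithelium and 27.0 CPM in the library labelled GFP (log2 ratio 4.21). Nos2 was at 2.57 and 17.1 CPM (2.73, 2.57 to 2.90), and Duox2, an epithelial oxidase, at 50.7 and 93.4 CPM (0.88, 0.84 to 0.93). Among hormone genes Gcg (-1.29, -1.34 to -1.24), Insl5 (79.3 and 35.9 CPM) and Cck (-1.59, -1.75 to -1.43) were lower in the library labelled GFP. The share of enteroendocrine-like cells was lower there too, at 1.89% against 4.14%, through the shallow clusters c28 and c29. Within that class the log2 ratios were smaller, at -0.32 for Gcg, -0.17 for Insl5 and -0.75 for Cck. Tac1, the gene of substance P, was higher, at 7.47 and 35.1 CPM (2.23, 2.13 to 2.33).

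The T cell genes Cd3g (10.9 and 0.313 CPM, log2 ratio -5.12), Trac (-5.16) and Gzmb (-5.08) were lower over all cells by more than the share of T/NK-like cells, which was 3.17% and 1.06%. The T/NK-like cells were also shallower in the library labelled GFP, with a median of 1897 UMIs against 4199.5. Share and depth together do not cover the drop, since these cells held 1448714 and 160568 UMIs in all, a smaller fall than that of the T cell genes. The identity of the 61 T/NK-like cells of the library labelled GFP was not checked apart from the cluster. The growth factor genes Ereg (-2.95, -3.37 to -2.56) and Areg (-0.89, -0.92 to -0.87) and the YAP target gene Cyr61 (-2.18, -2.23 to -2.12) were lower in the library labelled GFP. The haemoglobin gene Hbb-bs had 7451 UMIs in kept cells of the library labelled whole epithelium and 10 in those of the library labelled GFP.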
